A study of Mus musculus with 23 samples.

How the data were processed

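Gene expression was measured on mouse microarrays in 23 samples of microglia from the cortex and hippocampus, sorted per the labels as CD45 and CD11b positive cells. The samples fell into 6 groups. Wild-type C57BL6 mice (WT) gave 4 samples at 3 months and 4 at 12 months. The APPswlnd line (APP), which carries a human amyloid precursor protein transgene with familial Alzheimer mutations, gave 3 samples at 3 months and 4 at 12 months. The P301S line PS19 (TAU), which carries a human tau transgene with a frontotemporal dementia mutation, gave 4 samples at 3 months and 4 at the later age. The titles of these last 4 samples say 12 months, while their age and source fields say 9 months, and 9 months was used. The aged APP and TAU groups held the cells that the labels call active, sorted as Clec7a positive; Clec7a is a C-type lectin receptor. No such gate is named for the other groups, so that strain, pathology and gate differ together between aged transgenic and aged WT samples. The labels call the replicates biological but do not say that each came from a separate animal, so the p-values measure the spread between samples. The sex of the mice is not given.

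Total RNA was extracted with TriPure, and 5 ng was amplified, fragmented and biotinylated with a 3′ labelling kit for small amounts of RNA. The deposited values are log2 signals per probe set, made by the authors with RMA in the Transcriptome Analysis Console, as the submitters' processing notes state. RMA corrects background, normalizes between arrays and summarises the probes of each set. The notes give no versions, parameters or filters. The table held 22203 probe sets and no control probe sets, with values from 3.12 to 19.85. A symbol was available for 19572 probe sets and none for 2631, and the 19572 carried 19505 distinct symbols, of which 55 had more than 1 probe set. The genome build is not given in the sources used here, and no positions are printed. Clec7a, Xist and Ddx3y had no probe set with that symbol and were not analysed here, nor were some members of the gene lists, among them Spp1, Cd68 and Cd74. The transgenes carry human sequence, which probes for the mouse App and Mapt genes may not read. The number of arrays limits the precision: the median standard error (SE) of a log2 fold change was 0.226, or 0.244 where the 3 young APP samples entered.

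All 23 samples entered a single linear model with a mean per group in limma 3.58.1 (R 4.3.3, eBayes without trend), with 17 residual and 5.11 prior degrees of freedom. The values were used as deposited, with no further normalization and no filter on dim probe sets. Contrasts were two-sided, and a probe set was called at an adjusted p under 0.05 (Benjamini-Hochberg over all 22203 probe sets of the contrast). The contrasts were APP against WT and TAU against WT at 3 months, WT at 12 against 3 months, aged gated APP and aged gated TAU each against WT at 12 months, the gated groups against each other, and for each strain its change with age minus that of WT (the interaction). The groups, contrasts, gene lists, rule for named genes and main alternatives were fixed before the data were examined. On simulated data with the layout of the aged APP contrast, 61 of 100 probe sets shifted by 1 on the log2 scale and 97 of 100 shifted by 2 were called, along with 8 of the unshifted ones. That noise was independent between probe sets, so the 8 calls do not cover differences that run through whole arrays. Unchanged groups built from shuffled deviations of the real samples gave 7.11 higher calls on average in aged APP (594 at most). In aged TAU they gave 26.92 (1814 at most).

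The 26 gene lists covered genes of disease-associated microglia (DAM), homeostatic microglia, the type I interferon response, MHC class II, MHC class I, glycolysis and HIF1 targets, oxidative phosphorylation, cholesterol synthesis, lipid uptake, storage and efflux, lysosomes, NF-kB cytokines and chemokines, complement, the cell cycle, immediate early and heat shock responses, cytosolic ribosomal proteins and mouse orthologues of Alzheimer risk genes. They also covered markers of border and perivascular macrophages, monocytes, neutrophils, dendritic cells, T and NK cells, B cells, neurons, astrocytes, the oligodendrocyte lineage, and endothelial cells and pericytes. Some genes stand in more than 1 list, for example Apoe, Itgax, Ctsb, Slc2a1, Siglech, Ccl5 and Clu. Clec7a was left out of every list, since the aged APP and TAU samples were sorted on it. Each list was tested with limma's camera (preset inter-gene correlation of 0.01) against all other genes, on 1 probe set per symbol, with adjustment over the 26 lists. The same test with the correlation estimated from the data and limma's fry were run as alternatives. Members were also counted when adjusted over the list alone. Where the lower group of a called named gene lay at or below the 95th percentile of the chemosensory receptor probe sets in that group (7.73 to 8.14), taken as the level of background after seeing the data, the fold was computed against that percentile and is given as a lower bound. Where the signal of the higher group was no higher than that percentile, or the gene was not called and a group lay there, no size is given. This level lies above the median of every array (6.87 to 7.13), so a gene described as at background may still have a signal of its own. Genes were ranked by their fitted log2 fold changes.

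Named genes were, in each contrast, the 10 largest rises and 10 largest falls among called probe sets with 1 symbol and no overlap between the groups compared (for the interactions only the adjusted p applied, and predicted genes were left out), or the 5 smallest p-values where nothing was called. Up to 4 members per list with the smallest adjusted p were added, as well as Itgam, Ptprc, App, Mapt, Apoe, Trem2, P2ry12 and Tmem119 throughout. The agreement of the aged APP and TAU changes, which share the 4 WT samples, was set against 100 simulations of unchanged groups and against 6 assignments of the WT samples split between the comparisons. Probe sets called in an aged group were tested as sets in the young contrast of the same strain, which shares no sample with it. The alternatives were a trended and robust prior, fits on the compared groups alone, the replicate number as a block, a filter on dim probe sets, centring of each array, quantile normalization, array weights, a 2-fold minimum, probe sets with a symbol alone, the mean over all probe sets of a gene, and leaving out each sample in turn. Covariates for array spread, Y-linked signal and chemosensory receptor signal, and fits without certain samples, were added after seeing the data.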

Results

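The 23 arrays had medians between 6.87 and 7.13 and standard deviations (SD) between 2.40 and 2.60 on the log2 scale. The leading principal component, with 30.3% of the variance, separated all 8 aged gated samples from the other 15 samples. The next component, with 20.6%, had multicopy Y probe sets such as Sly and Ssty1 at its high end and genes such as Camk2a, Aldoc, Clu and Sparcl1 at its low end, and also followed the spread of the arrays (r = -0.71 over the samples). WT 12 months replicates 2 and 4 stood apart at its high end and had the highest multicopy Y medians, 13.86 and 12.73, and the highest chemosensory receptor median among WT samples, 6.32 each. Component 3, with 12.9%, followed the mean of the Y-linked genes Kdm5d, Uty and Eif2s3y (r = 0.91 over the samples). Kdm5d, a Y-linked histone demethylase, was at 7.81 ± 0.33 (SD, n = 4) in young WT, 4.14 ± 0.31 (n = 3) in young APP and 5.19 ± 1.70 (n = 4) in young TAU. In the aged groups it was at 7.50 ± 0.86 in WT, 6.18 ± 1.74 in gated APP and 6.06 ± 1.48 in gated TAU (n = 4 each). Of the sort markers, Ptprc, which encodes CD45, was called in no comparison. Itgam, which encodes CD11b, was at 14.83 ± 0.23 in aged WT and lower in gated APP (14.02 ± 0.18, adjusted p = 0.0363) and gated TAU (13.68 ± 0.19, adjusted p = 0.00314).

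The comparisons at 3 months ask how the transgenic strains differ from WT at the age the labels call pre-pathology. In young APP microglia the homeostatic genes P2ry12, an ADP receptor, and Tmem119, a membrane protein typical of microglia, were near their WT levels. P2ry12 was at 18.18 ± 0.06 against 18.21 ± 0.15 (SD, n = 3 and 4) and Tmem119 at 14.17 ± 0.66 against 14.43 ± 0.68. Apoe, which encodes the lipid carrier apolipoprotein E, was at 12.00 ± 0.36 against 11.20 ± 0.91, a difference within the spread of the samples. With limma, 0 probe sets were called, and 648 had an unadjusted p under 0.05 where 1110 would by chance. A fit on these 7 samples alone called 93, of which 92 were lower in APP, and 22 of the 23 with a symbol lie on the Y chromosome. Array weights gave 8 calls. The smallest p-values belonged to a probe set with no symbol, Kdm5d, Tceal3, Uty and Slc10a2, each with an adjusted p of 1. The main fit shares 1 spread per probe set over all 6 groups, so its 0 calls depend on the groups not compared here. Kdm5d had an SD of 0.33 and 0.31 in young WT and young APP, but of 1.70 in young TAU, 1.74 in gated APP and 1.48 in gated TAU. Kdm5d and Uty fell to background in APP, Uty from 8.84 ± 0.51 in WT, and Tceal3 and Slc10a2 were at background in both groups. The sex of the mice may thus differ between these groups along with strain.

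Camera called 9 lists in young APP mice, none of them with an estimated correlation or with fry. Immediate early and heat shock genes lay lower, with a median log2 fold change of -0.32 over 29 measured genes (adjusted p = 5.34e-10, and adjusted p = 0.0701 with an estimated correlation). Border macrophage markers lay higher, with a median of 0.27 (adjusted p = 0.000222, and adjusted p = 0.0701 with an estimated correlation). The transcription factors Klf2 and Klf6 were among the lower genes at log2 fold changes of -1.39 ± 0.46 and -0.69 ± 0.23 (SE), and Cbr2 among the higher markers at 0.69 ± 0.41, none of these genes called. The other lists called had smaller or more variable shifts. They were ribosomal protein genes (median -0.21, adjusted p = 0.652 with an estimated correlation), MHC class II (-0.26, adjusted p = 0.139 with it), and oxidative phosphorylation (-0.12, adjusted p = 0.789 with it). Calls were also made for NF-kB genes (-0.16, adjusted p = 0.602 with it), and neutrophil (-0.34, adjusted p = 0.374 with it), dendritic cell (-0.12, adjusted p = 0.307 with it) and astrocyte markers (0.37, adjusted p = 0.652 with it). No list held a called gene when adjusted over the list alone. DAM genes had a median of -0.07 (adjusted p = 0.489). Leaving out APP replicate 2 left 3 lists and turned the ribosomal protein (adjusted p = 0.487) and oxidative phosphorylation lists (0.214) the other way. With the Y-linked mean as a covariate the oxidative phosphorylation (adjusted p = 0.00128), NF-kB (0.0364) and ribosomal protein lists (0.279) pointed up.

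In young TAU microglia P2ry12, Apoe and Trem2 were near their WT levels. P2ry12 was at 18.30 ± 0.05 against 18.21 ± 0.15, Apoe at 11.16 ± 0.56 against 11.20 ± 0.91 and Trem2, a lipid-sensing receptor of microglia, at 14.53 ± 0.30 against 14.81 ± 0.42 (SD, n = 4 each). With limma, 0 probe sets were called, and 922 had an unadjusted p under 0.05 where 1110 would by chance. The smallest p-values were those of Actl10, the chemokine receptor gene Ccr6, Tceal3 and 2 probe sets with no symbol, at adjusted p from 0.762 to 0.906. Ccr6 was at 10.27 ± 2.97 in TAU and at background in WT, and Actl10 and Tceal3 were at background in both groups. The Y-linked gene Uty was at 5.18, 4.62 and 4.29 in TAU replicates 2, 3 and 4, but at 8.58 in replicate 1 and 8.25 to 9.50 in WT. The multicopy Y medians of these 3 samples were 6.48, 6.23 and 6.53, against 10.64 in replicate 1 and 8.64 to 10.79 in WT. Mapt, the mouse tau gene, was at background in both groups (adjusted p = 0.906 in this comparison and not called in any other).

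Camera called 5 lists in young TAU mice, all lower and none with an estimated correlation or with fry. Immediate early and heat shock genes had a median of -0.22 (adjusted p = 9.52e-09, and adjusted p = 0.218 with an estimated correlation), with Klf6 at -0.87 ± 0.22 (log2 fold change, SE) and Hspa1a, a heat shock protein gene, at -1.69 ± 0.63. Of these 29 genes 1 fell when adjusted over the list alone. Lysosome genes (median -0.17, adjusted p = 0.669 with an estimated correlation), NF-kB genes (-0.10, adjusted p = 0.669 with it), lipid genes (-0.09, adjusted p = 0.524 with it) and Alzheimer risk genes (-0.13, adjusted p = 0.669 with it) were the others. The cytokine genes Il1b and Tnf were at -1.18 ± 0.35 and -0.98 ± 0.39, and Npc1, a lysosomal cholesterol transporter, fell to background, none of them called. DAM genes had a median of -0.11 (adjusted p = 0.106). The number of lists called was 1 without TAU replicate 4, 9 without TAU replicate 1 or 2, and 10 without WT replicate 1. With the Y-linked mean as a covariate the lipid, lysosome, NF-kB and risk lists pointed the other way, at adjusted p from 0.0963 to 0.975.

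The comparison of WT mice at 12 and 3 months gives the change with age without transgene and with no Clec7a gate named. It called 8 probe sets with limma, all higher at 12 months, and 1987 had an unadjusted p under 0.05. The 5 with a symbol were Ica1, Ildr2, Lsp1, Elf3 and Fmo1, of which all but Lsp1 were at the level of background at 3 months and Elf3 and Fmo1 also at 12 months. Ica1, an islet cell autoantigen gene, went from 6.33 ± 0.42 to 8.34 ± 0.29 (SD, n = 4 each; adjusted p = 0.0113), and Lsp1, a leukocyte actin-binding protein gene, from 10.38 ± 0.52 to 11.66 ± 0.40 (adjusted p = 0.0357). Without WT 12 months replicate 3 the count was 88, and without WT 3 months replicate 2 or replicate 3 it was 0. It was 3 without WT 3 months replicate 1 or WT 12 months replicate 4, 4 without WT 12 months replicate 2, and 5 without WT 3 months replicate 4 or WT 12 months replicate 1. With WT 12 months replicates 2 and 4 both left out the count was 1, and with each array centred on its median it was 3. Il1b was at 15.17 ± 0.62 against 13.48 ± 0.51 and was not called (adjusted p = 0.149), though it was the 1 NF-kB gene to rise when adjusted over the list alone. Neu1, a lysosomal sialidase gene, was at 7.72 ± 0.35 against 8.78 ± 0.37 and Grn, the progranulin gene, at 18.36 ± 0.03 against 18.90 ± 0.13, and 2 lysosome genes fell when adjusted over the list alone.

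Camera called 4 lists with age in WT, and neither the estimated correlation nor fry called any. Immediate early genes (median -0.29, adjusted p = 0.792 with an estimated correlation), lysosome genes (-0.09, adjusted p = 0.812 with it) and Alzheimer risk genes (-0.17, adjusted p = 0.792 with it) lay lower. Ribosomal protein genes lay higher (0.18, adjusted p = 0.815 with it). DAM genes had a median of 0.06 (adjusted p = 0.253) and homeostatic genes a median of -0.06 (adjusted p = 0.213). No other list was called. Leaving out WT 3 months replicate 2 left 1 list, and leaving out WT 3 months replicate 3 or WT 12 months replicate 4 left 2. Without both WT 12 months replicates 2 and 4 the lysosome and Alzheimer risk lists pointed the other way.

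Gated APP microglia at 12 months were compared with WT microglia of the same age, the contrast that shows the active cells of the amyloid model. The largest rises against a WT signal above background were those of Igf1, the gene of insulin-like growth factor 1, Cst7, which encodes the cathepsin inhibitor cystatin F, and Apoe. Igf1 was 242-fold higher (log2 fold change 7.92 ± 0.26, SE; 16.74 ± 0.39 against 8.82 ± 0.15, SD, n = 4 each; adjusted p = 1.36e-15), Cst7 231-fold and Apoe 179-fold. The receptor tyrosine kinase gene Axl, whose signal in WT was at the level of background, was at least 64.2-fold higher. The largest falls were those of Bank1 (16.2-fold; -4.02 ± 0.28, adjusted p = 5.5e-10), the integrin gene Itga9 (11.1-fold), Tmem119 (9.9-fold), Arrdc3 and Stab1. With limma, 2015 probe sets were called, 1243 higher and 772 lower, and 1172 of them differed at least 2-fold. Among the called genes named for this contrast, all 4 gated samples lay beyond all 4 WT samples except for Ube2c, Fn1, Ace and Pecam1. For the 10 largest rises and falls this was a condition of being named. Over all called probe sets it held for 1676 of 2015, and over all 22203 probe sets for 2565. The NADPH oxidase gene Cybb rose by 5.65 on the log2 scale. From a WT signal at background, the fatty acid binding protein genes Fabp3 and Fabp5 rose at least 48.2-fold and 40-fold, Etl4 at least 28.4-fold, the CD11c gene Itgax at least 13.4-fold and Cd200r4 at least 5.26-fold. Upk1b (-3.09), Crybb1 (-2.77) and the potassium channel gene Kcnd1 (-2.72) also fell, and Epha2 and Ecscr fell to background, at least 3.77-fold and 2.23-fold.

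**Figure D1:**
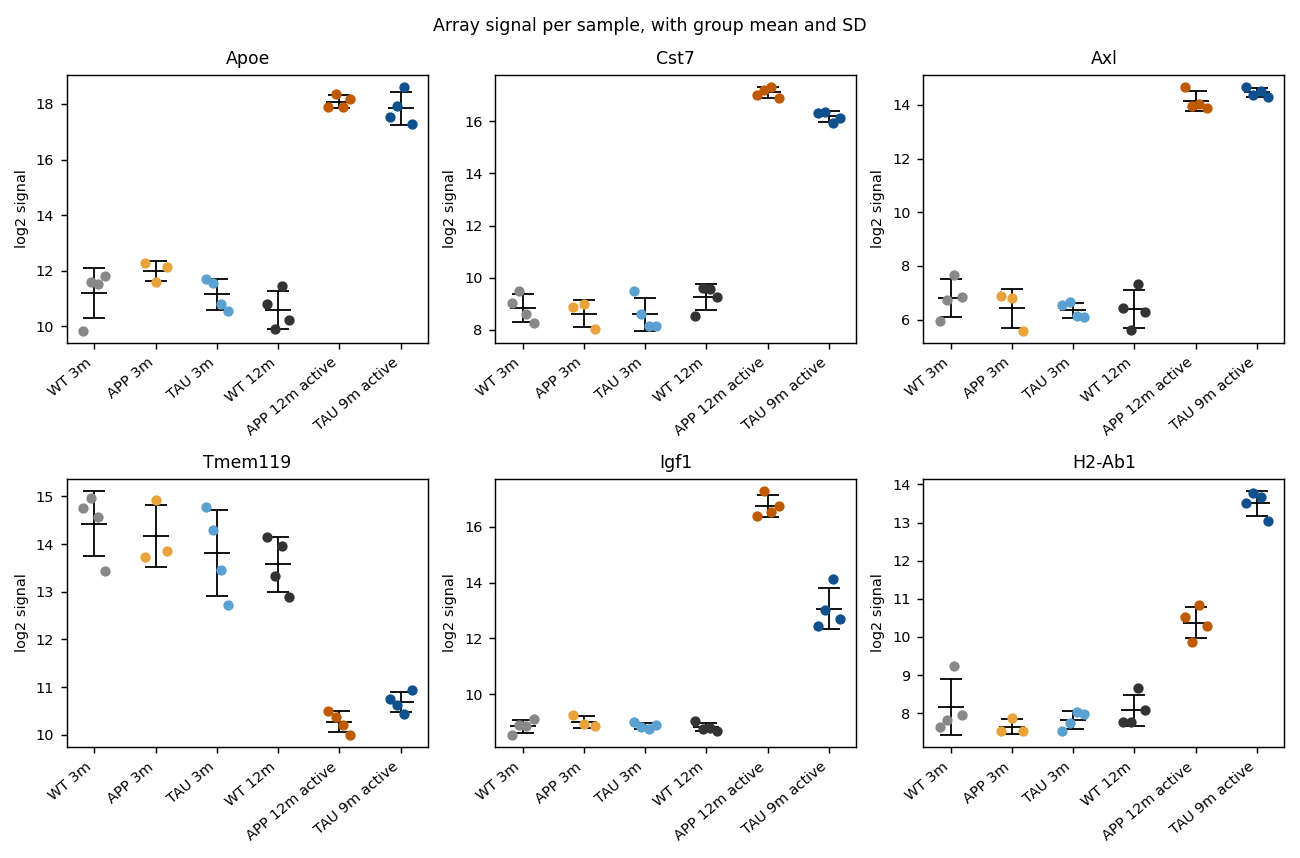
Array signal on the log2 scale of Apoe, Cst7, Axl, Tmem119, Igf1 and H2-Ab1 in each of the 23 samples (points), with the group mean and SD (bars), by group. In the gated aged APP and TAU groups Apoe, Cst7, Axl and Igf1 lay above every other sample and Tmem119 below, while Igf1 was highest in APP and H2-Ab1 highest in TAU.

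Of 34 measured DAM genes, 32 rose and none fell (33 rose when adjusted over the list alone; median log2 fold change 2.61, camera adjusted p = 2.19e-71, and adjusted p = 4.32e-06 with an estimated correlation). The APP cells were selected by the Clec7a gate and no such gate is named for the WT cells, so the gate itself may account for part of this rise. Of 28 homeostatic genes, 17 fell, among them P2ry12 (-1.27 ± 0.14), Txnip (-1.89 ± 0.17) and the adhesion receptor gene Adgrg1 (-2.0 ± 0.22). When adjusted over the list alone 21 fell, and the list was lower (median -0.89, adjusted p = 0.0127 with an estimated correlation). Type I interferon response genes rose in 23 of 34 cases (33 when adjusted over the list alone; median 1.26, adjusted p = 0.000672 with an estimated correlation), with Ifi204 47.5-fold, Ifitm3 38.8-fold and Slfn5 at least 15-fold higher. Trem2 rose 3.07-fold (adjusted p = 1.41e-05).

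The glycolysis and HIF1 target genes rose in 18 of 23 cases (19 when adjusted over the list alone; median 1.26, adjusted p = 2e-05 with an estimated correlation). Egln3, a prolyl hydroxylase induced by HIF1, rose at least 14.6-fold, Hif1a itself 8.47-fold and Tpi1, which encodes the glycolytic enzyme triosephosphate isomerase, 11.4-fold. Of 20 cholesterol synthesis genes 10 rose and 1 fell (14 and 1 when adjusted over the list alone; median 0.75, adjusted p = 0.000354 with an estimated correlation), with Fdps, which encodes farnesyl diphosphate synthase, at least 1.99-fold, Msmo1 at least 1.28-fold and Cyp51 at least 1.05-fold higher, each from a WT signal at background. Among 24 lipid uptake, storage and efflux genes 10 rose and 2 fell (12 and 2 when adjusted over the list alone; median 0.60, adjusted p = 0.00339 with an estimated correlation), including the lipid droplet gene Plin2, 20.5-fold higher. Lysosome genes rose in 16 of 33 cases and fell in 1 (22 and 3 when adjusted over the list alone; median 0.72, adjusted p = 0.0313 with an estimated correlation), with Cd63 at 2.58 ± 0.25, the beta-glucuronidase gene Gusb at 2.40 ± 0.24 and the cathepsin gene Ctsz at 2.11 ± 0.23.

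MHC class I genes rose in 7 of 13 cases (9 when adjusted over the list alone; median 0.69, adjusted p = 0.0169 with an estimated correlation), with H2-D1 6.0-fold and H2-K1 3.35-fold higher. MHC class II genes rose in 4 of 9 cases, and when adjusted over the list alone 4 rose and 1 fell (median 0.76, adjusted p = 0.0168 with an estimated correlation); H2-Ab1 rose at least 4.7-fold. NF-kB cytokine and chemokine genes rose in 11 of 26 cases (13 when adjusted over the list alone; median 0.67, adjusted p = 0.0127 with an estimated correlation), among them Il1rn, which encodes the interleukin 1 receptor antagonist (at least 4.81-fold), and the prostaglandin synthase gene Ptgs2 (15.4-fold). Immediate early and heat shock genes fell in 17 of 29 cases and rose in 1 (21 and 1 when adjusted over the list alone; median -1.29, adjusted p = 0.0148 with an estimated correlation), with Jun at -1.81 ± 0.19 and Fos at -1.74 ± 0.25.

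Camera called 6 further lists in gated APP microglia whose calls were lost with an estimated correlation. Ribosomal protein genes rose in 22 of 32 cases (29 when adjusted over the list alone; median 0.83, adjusted p = 0.0622 with an estimated correlation). Rpl23 was at 1.62 ± 0.25. Oxidative phosphorylation genes rose in 21 of 43 (33 when adjusted over the list alone; median 0.69, adjusted p = 0.0693 with it), with Ndufa1 at 2.45 ± 0.26. Complement genes rose in 3 of 15 cases and fell in 1 (8 and 1 when adjusted over the list alone; median 0.51, adjusted p = 0.0597 with an estimated correlation), with C4b at 0.93 ± 0.25. Cell cycle genes rose in 4 of 33 cases, the same number when adjusted over the list alone (median 0.22, adjusted p = 0.0688 with an estimated correlation): Cdk1, Mki67, Ube2c and Ccnb2. Of these 4 genes Cdk1, Mki67 and Ube2c stayed at the level of background in both groups, and Ccnb2 was at least 1.12-fold higher. Neutrophil markers had a median of -0.36 (adjusted p = 0.268 with an estimated correlation; S100a8 fell between levels at background) and dendritic cell markers a median of -0.32 (adjusted p = 0.1 with it).

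The Alzheimer risk genes were not called as a list (adjusted p = 0.448): 7 rose and 7 fell, with a median of -0.13 and a mean of 0.23, so that median and test differed in sign. Apoe, Ctsb, Scimp (at least 1.5-fold) and Trem2 were among the 7 that rose. Border macrophage markers were not called (median -0.21, adjusted p = 0.0682): 2 rose, Colec12 and Folr2, to signals no higher than the WT background, and 3 fell, including Stab1 (-3.16 ± 0.36) and Maf (at least 1.34-fold). Markers of monocytes (2 of 15 rose; adjusted p = 0.496), T and NK cells (2 of 17 fell; 0.152) and B cells (1 of 8 rose; 0.672) were not called as lists. Nor were those of neurons (0 of 18 called; 0.595), astrocytes (1 of 15 rose, Gfap, to a signal no higher than the WT background; 0.754), oligodendrocytes (0 of 14 called; 0.592) and endothelial cells and pericytes (2 rose and 1 fell of 15; 0.0622). Strain, pathology and gate differ together in this contrast, and Y-linked signal was low in gated APP replicate 4. The 2015 calls became 1326 in a fit on the compared groups alone and 1264, of which 627 were higher, without WT replicates 2 and 4.

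Gated TAU microglia at 9 months were compared with the same WT samples, the contrast that shows the active cells of the tau model. Axl was at least 80.1-fold higher (log2 fold change 8.06 ± 0.34, SE; 14.47 ± 0.17 against 6.41 ± 0.71, SD, n = 4 each; adjusted p = 1.53e-13), Apoe 151-fold, Cst7 122-fold and Itgax at least 29.8-fold. The MHC class II gene H2-Ab1 rose at least 41.1-fold, from 8.07 ± 0.41 to 13.50 ± 0.32. Mmp12, a macrophage elastase gene, rose at least 43.8-fold and Olr1, a receptor gene for oxidised lipoprotein, at least 9.53-fold, and Cybb, Ifi211 and Ifi204 were the others among the 10 largest fitted rises. The falls were led by Bank1 (14.8-fold), the fructose transporter gene Slc2a5 (9.29-fold), Crybb1 (9.06-fold) and Tmem119 (7.4-fold), followed by Upk1b, Gpr165, Tsc22d3, Itga9, Il7r and Khdrbs3. With limma, 1946 probe sets were called, 1131 higher and 815 lower, and 993 of them differed at least 2-fold. All 4 gated samples lay beyond all 4 WT samples for the called genes named, except Klrb1c and Grin2b. For the 10 largest rises and falls this was a condition of being named. Over all called probe sets it held for 1604 of 1946, and over all 22203 probe sets for 2649.

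Of 34 DAM genes 30 rose in gated TAU microglia (33 when adjusted over the list alone; median log2 fold change 2.29, camera adjusted p = 3.44e-65, and adjusted p = 8.15e-06 with an estimated correlation). Homeostatic genes fell in 17 of 28 cases, the same number when adjusted over the list alone (median -0.79, adjusted p = 0.0133 with an estimated correlation), with P2ry12 at -1.43 ± 0.14 and Slc2a5 at -3.22 ± 0.28. Interferon response genes rose in 24 of 34 cases (28 when adjusted over the list alone; median 1.44, adjusted p = 0.000892 with an estimated correlation), with Ifi204 49.4-fold and Ifitm3 25.3-fold higher. MHC class II genes rose in 6 of 9 cases (7 when adjusted over the list alone; median 1.58, adjusted p = 0.000151 with an estimated correlation), with H2-Eb1 39.0-fold and H2-Aa 15.5-fold higher. MHC class I genes rose in 6 of 13 cases (8 when adjusted over the list alone; median 0.74, adjusted p = 0.0305 with an estimated correlation). NF-kB genes rose in 12 of 26 cases and fell in 1 (15 and 1 when adjusted over the list alone; median 0.88, adjusted p = 0.00591 with an estimated correlation), with Il1rn at least 3.96-fold, Cxcl2 at least 10-fold and Cxcl16 5.38-fold higher. Complement genes rose in 8 of 15 cases and fell in 1 (8 and 2 when adjusted over the list alone; median 0.67, adjusted p = 0.0133 with an estimated correlation), among them the factor B gene Cfb at 2.11-fold or more.

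Lipid uptake, storage and efflux genes rose in 11 of 24 cases and fell in 1 (15 and 1 when adjusted over the list alone; median 0.72, adjusted p = 0.00151 with an estimated correlation), with Fabp5 at least 8.44-fold and Plin2 11.5-fold higher. Glycolysis and HIF1 target genes rose in 11 of 23 cases (13 rose and 1 fell when adjusted over the list alone; median 0.80, adjusted p = 0.00279 with an estimated correlation), with Hif1a at 1.71 ± 0.21. Egln3 was called higher in TAU, from 6.54 to 8.10, but stayed below the WT background of 8.14, so no size is given. Cholesterol synthesis genes were not called as a list (median -0.01, adjusted p = 0.867); Pmvk rose, between levels at background, and Mvd fell, and the same 1 and 1 were counted when adjusted over the list alone. Immediate early and heat shock genes fell in 15 of 29 cases and rose in 2 (17 and 2 when adjusted over the list alone; median -1.07, adjusted p = 0.0171 with an estimated correlation). Lysosome genes rose in 15 of 33 cases and fell in 1 (17 and 1 when adjusted over the list alone; median 0.51, adjusted p = 0.0556 with an estimated correlation). Ribosomal protein genes rose in 22 of 32 (27 when adjusted over the list alone; median 0.72, adjusted p = 0.0682 with it) and oxidative phosphorylation genes in 16 of 43 (25 when adjusted over the list alone; median 0.67, adjusted p = 0.107 with it).

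Among the Alzheimer risk genes 9 rose and 2 fell in gated TAU microglia; camera called the list higher (adjusted p = 0.044, and adjusted p = 0.53 with an estimated correlation), while the median was -0.05 and the mean 0.42. Scimp rose at least 3.37-fold and Ms4a7, of the MS4A family of membrane proteins, 11.8-fold. Border macrophage markers were not called (median 0.14, adjusted p = 0.836), and Stab1 alone among them fell. Neutrophil markers had a median of -0.49 (adjusted p = 0.0207, and adjusted p = 0.38 with an estimated correlation). Cell cycle genes (1 of 33 rose, Cdk1, between levels at background; adjusted p = 0.273) were not called as a list. Nor were markers of monocytes (2 of 15 rose; 0.636), dendritic cells (2 of 12 fell; 0.124) and T and NK cells (2 rose and 1 fell of 17; 0.822). Markers of B cells (1 of 8 rose; 0.384), neurons (1 of 18 rose; 0.135), astrocytes (0 of 15 called; 0.156), oligodendrocytes (0 of 14 called; 0.89) and endothelial cells (1 of 15 rose; 0.318) were not called as lists. The T and NK cell and oligodendrocyte lists had medians of -0.09 and -0.03 while their tests pointed up, and the monocyte markers had a median of -0.03 and a mean of 0.14. The TAU samples were 3 months younger than the WT samples, and strain, pathology and gate differed as well. Y-linked signal was low in gated TAU replicates 3 and 4. The 1946 calls became 1218 in a fit on the compared groups alone and 1227, of which 518 were higher, without WT replicates 2 and 4.

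**Figure D2:**
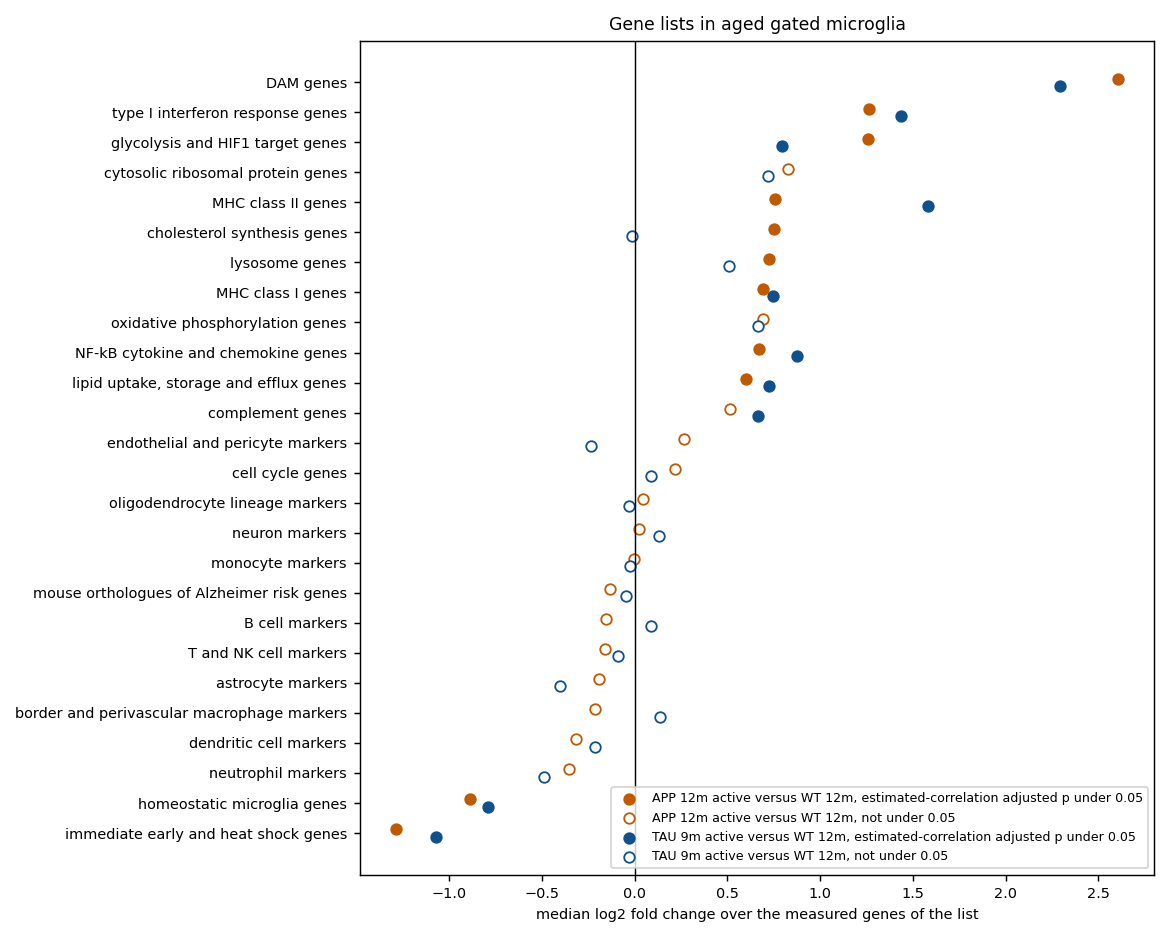
Median log2 fold change of each of the 26 gene lists (points) in aged gated APP and aged gated TAU microglia, each against WT at 12 months, with filled points where camera gave an adjusted p under 0.05 with an estimated correlation. DAM genes had the highest medians, 2.61 in APP and 2.29 in TAU, and cholesterol synthesis genes had 0.75 in APP against -0.01 in TAU.

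The aged APP and TAU changes were set side by side to see how far they ran together. Across the 22203 probe sets, which are not independent replicates, their correlation was 0.854, and 779 probe sets were higher in both, 457 lower in both and 2 called in opposite directions. Unrelated lists of these sizes would share 63.32 and 28.34. The comparisons share their 4 WT samples: simulated unchanged groups gave a mean correlation of 0.502 and up to 0.917, which is above the observed value, and shared 507 higher calls at most. The covariance was 0.320, against 0.0462 on average and 0.257 at most in the simulations, a difference of 0.274 from the average. With the WT samples split between the comparisons the correlation lay between 0.442 and 0.740, and between 389 and 469 probe sets were higher in both. Both transgenic groups were also sorted as Clec7a positive, while no such gate is named for the WT samples. A shared effect of the gate may therefore add to the agreement, and neither the simulations nor the splits remove it.

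The 1243 probe sets called higher in aged gated APP microglia had a median log2 fold change of -0.07 in the young APP comparison (camera p = 0.00308, and p = 0.486 with an estimated correlation), and the 772 called lower had a median of 0.02 (camera p = 0.876). For TAU the 1131 higher sets had a median of -0.08 at 3 months (camera p = 0.000119, and p = 0.361 with an estimated correlation) and the 815 lower sets a median of 0.01, with the test pointing down (camera p = 0.437). The camera value of the higher APP sets became 0.125 without WT replicate 2 and 0.338 without APP replicate 2. That of the higher TAU sets became 0.556 without TAU replicate 4, and that of the lower APP sets 0.0401 without APP replicate 1.

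The gated groups were compared with each other to see where active microglia of the amyloid and tau models differ; no WT sample and no difference in gate enters. Gated APP microglia had more Igf1 (12.7-fold; 16.74 ± 0.39 against 13.07 ± 0.74, SD, n = 4 each; log2 fold change 3.67 ± 0.26, SE, adjusted p = 8.43e-09) and more Egln3 (15.1-fold; adjusted p = 3.01e-10), along with genes of glycolysis and cholesterol synthesis. Gated TAU microglia had more of the MHC class II genes H2-Eb1 (23.1-fold; 14.15 ± 0.19 against 9.63 ± 0.48; adjusted p = 3.48e-08) and H2-Ab1 (8.75-fold), more Olr1 (at least 12.4-fold) and more Cfb (at least 2.74-fold). With limma, 206 probe sets were called, 139 higher in APP and 67 lower, and 172 differed at least 2-fold. The balance moved with the array SD as a covariate, to 165 higher and 132 lower. For every called gene named here the 4 samples of each group did not overlap. For the 10 largest rises and falls this was a condition of being named. Over all called probe sets it held for 194 of 206, and over all 22203 probe sets for 1044. Apoe (adjusted p = 0.949), Trem2 (0.161), P2ry12 (0.848) and Tmem119 (0.844) were not called.

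**Figure D3:**
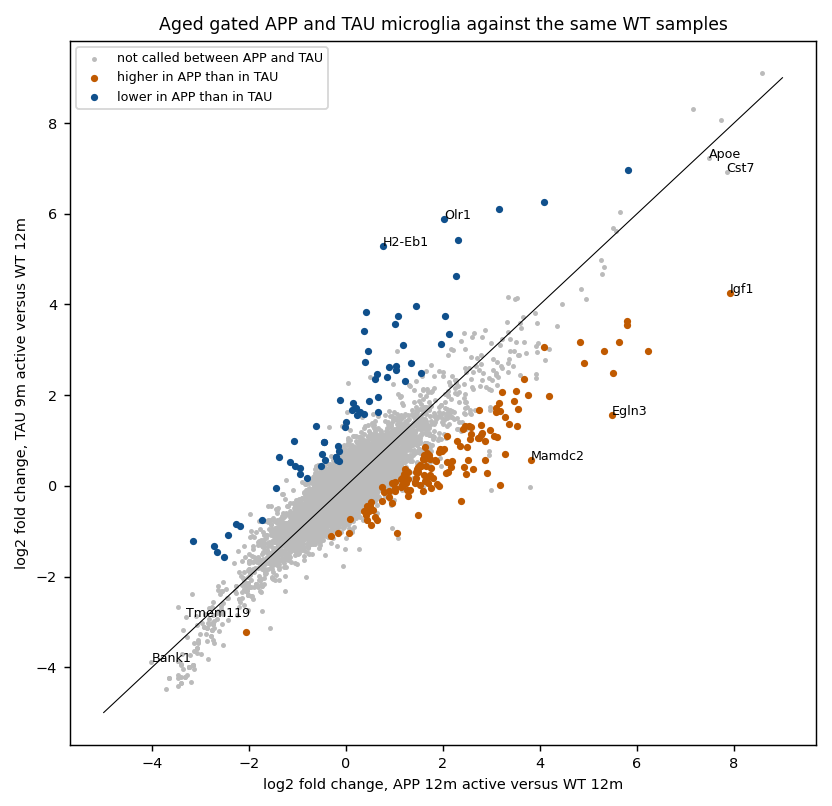
Log2 fold change against WT at 12 months of each probe set in gated APP (horizontal axis) and gated TAU microglia (vertical axis), with the 139 probe sets called higher and the 67 called lower in APP than in TAU coloured, and a line where both changes are equal. Both axes use the same 4 WT samples, so the points would follow the line in part without any effect. The Clec7a gate of both transgenic groups may add to this. Igf1 and Egln3 lie on the APP side and H2-Eb1 and Olr1 on the TAU side.

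Cholesterol synthesis genes were higher in gated APP than in gated TAU microglia: 6 of 20 were called and none lower (14 when adjusted over the list alone; median log2 difference 0.77, camera adjusted p = 1.58e-23, and adjusted p = 5.35e-06 with an estimated correlation). Fdps was at 9.14 ± 0.16 against 7.62 ± 0.24 (adjusted p = 1.15e-05), at least 2.41-fold since the TAU signal was at background. The sterol enzyme gene Sc5d differed by 2.11 ± 0.30 (SE), and Msmo1 and Cyp51, also at background in TAU, were at least 1.55-fold and 1.27-fold higher in APP. Glycolysis and HIF1 target genes were higher in APP in 8 of 23 cases (14 when adjusted over the list alone; median 0.81, adjusted p = 2.81e-24, and adjusted p = 3.57e-05 with an estimated correlation), including Ero1a (2.03 ± 0.28), Hif1a (1.37 ± 0.21) and the lactate dehydrogenase gene Ldha (1.02 ± 0.17). MHC class II genes were lower in APP in 4 of 9 cases and higher in 1, H2-Ob (6 and 1 when adjusted over the list alone; median -0.81, adjusted p = 1.61e-11, and adjusted p = 0.000207 with an estimated correlation). Of 15 endothelial markers 2 were higher in APP, Slc2a1, a glucose transporter gene held by both lists, and Flt1, at least 2.9-fold (median 0.52, adjusted p = 3.83e-06, and adjusted p = 0.145 with an estimated correlation). The endothelial list mean was 8.96 and 8.31 in APP replicates 2 and 3, but 7.52 and 7.73 in replicates 1 and 4, beside 7.46 to 7.61 in TAU. Border macrophage markers moved with the MHC class II genes: Stab1 (-1.95 ± 0.36) and Mrc1 (-1.68 ± 0.37) were lower in APP and Colec12 higher, between levels at background (median -0.30, adjusted p = 0.00154, and adjusted p = 0.0719 with an estimated correlation).

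**Figure D4:**
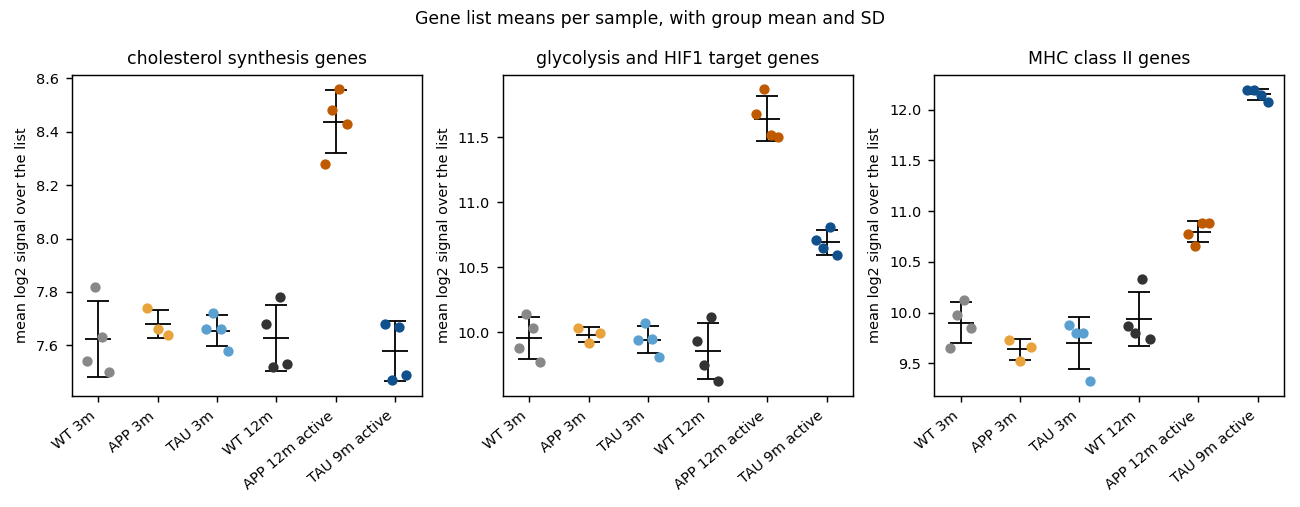
Mean log2 signal over the measured genes of the cholesterol synthesis, glycolysis and HIF1 target, and MHC class II lists in each of the 23 samples (points), with the group mean and SD (bars). Cholesterol synthesis stood at 8.44 ± 0.12 in gated APP and 7.58 ± 0.11 in gated TAU, glycolysis and HIF1 targets at 11.64 ± 0.17 and 10.69 ± 0.09, and MHC class II at 10.80 ± 0.11 and 12.15 ± 0.05 (SD, n = 4 each).

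Among 34 DAM genes, 6 were higher in APP, including Igf1, Gpnmb (3.03 ± 0.38), Mamdc2 (at least 6.17-fold) and Dkk2 (at least 1.03-fold), and Itgax was lower (-1.15 ± 0.22). When adjusted over the list alone 10 were higher and 4 lower, and the list call (median 0.11, adjusted p = 0.00154) had an adjusted p = 0.29 with an estimated correlation. The lipid genes were split, with Fabp3 and Fabp5 higher in APP by 2.47 ± 0.30 and 2.24 ± 0.29. The cholesterol exporter gene Abca1 was lower (-1.49 ± 0.28), as was the scavenger receptor gene Cd36, between levels at background; the list was not called (median 0.14, adjusted p = 0.168). Lysosome genes (2 of 33 higher; median 0.17, adjusted p = 0.679 with an estimated correlation) and complement genes (2 of 15 lower; -0.20, adjusted p = 0.23 with it) were called at the preset correlation alone. So were T and NK cell markers (1 of 17 lower; -0.14, adjusted p = 0.181 with it) and B cell markers (0 of 8 called; -0.27, adjusted p = 0.181 with it). Of the Alzheimer risk genes 4 were lower in APP, Ms4a7, Abca1, Ms4a6d and Scimp, with a median of 0.01 and a mean of -0.19 for a list that was not called (adjusted p = 0.0884). Other genes among the largest fitted differences were Etl4, Adarb1, Plp2 (at least 5.81-fold) and Lgi2 (at least 1.23-fold), higher in APP. The heparanase gene Hpse was also higher, between levels at background. Postn, Siglecf, Ccl9 and Mmp2 were lower in APP. Interferon genes (adjusted p = 0.157), homeostatic genes (0.536), MHC class I genes (0.43), NF-kB genes (0.416), immediate early genes (0.43), ribosomal protein genes (0.619), oxidative phosphorylation genes (0.199) and cell cycle genes (0.0884) were not called, nor were the remaining cell type lists. Strain and 3 months of age differ together here, and a fit on these 8 samples alone called 120 probe sets.

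The interactions ask which differences between transgenic and WT mice were larger at the later age than at 3 months. A gate is named at the later age alone. Y-linked signal was also uneven: Kdm5d was at 4.14 ± 0.31 in young and 6.18 ± 1.74 in gated APP. It was at 5.19 ± 1.70 and 6.06 ± 1.48 in TAU, and at 7.81 ± 0.33 and 7.50 ± 0.86 in WT (SD). Sex may thus differ together with strain and age here. For APP 844 probe sets were called, 627 with a more positive and 217 with a more negative change than in WT. Cst7 (log2 difference of changes 8.08 ± 0.45, SE), Igf1 (7.76 ± 0.38, adjusted p = 8.25e-12), Apoe (6.68 ± 0.57) and Ifitm3 were on the positive side. So were Axl, Etl4, Itgax and Cd200r4, whose signals in the young groups and in aged WT were at the level of background, so that their differences have no exact size. Bank1 (-4.27 ± 0.41), Itga9 (-4.03 ± 0.43), Stab1 (-3.45 ± 0.52) and Tmem119 (-3.04 ± 0.56) were on the negative side. Trem2 had a difference of 1.99 ± 0.32 and P2ry12 -1.25 ± 0.20. For TAU 832 probe sets were called, 577 more positive and 255 more negative. They included Apoe (7.28 ± 0.55), Cst7 (7.18 ± 0.43), Cybb (6.05 ± 0.39) and H2-Eb1 (5.99 ± 0.49), as well as Axl and Itgax from signals at background, on 1 side and Bank1 (-4.13 ± 0.39), Itga9, Slc2a5 and Gpr165 on the other.

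With an estimated correlation 12 lists were called in the APP interaction and 10 in the TAU interaction, of 16 and 14 with the preset one. DAM genes were more positive in 28 of 34 cases in each strain (medians 2.71 and 2.54, adjusted p = 3.91e-06 and 1.11e-05 with an estimated correlation). Homeostatic genes were more negative in 14 of 28 cases in APP and 10 in TAU (medians -0.89 and -0.84, adjusted p = 0.0162 and 0.0316 with it). Cholesterol synthesis genes were more positive in 6 of 20 cases in APP (median 0.68, adjusted p = 0.0015 with it) and in none in TAU (median -0.02, adjusted p = 0.724). MHC class II genes were so in 2 of 9 cases in APP and 4 in TAU (medians 1.04 and 1.48, adjusted p = 0.00644 and 0.000151 with it). Immediate early genes had medians of -0.74 in APP (adjusted p = 0.146 with an estimated correlation) and -0.44 in TAU (adjusted p = 0.277 with it). The APP count was 447 and the TAU count 502 with the Y-linked mean as a covariate, and 1575 and 1460 with array weights. Without TAU 3 months replicate 3 the TAU count was 541, without WT 12 months replicate 3 it was 1356, and without WT 12 months replicates 2 and 4 it was 464. The balance of directions also moved: in APP 655 were more positive and 457 more negative with the receptor median as a covariate, 648 and 437 with the array SD, 343 and 234 without WT 12 months replicates 2 and 4, and 845 and 345 without WT 12 months replicate 3. In TAU these were 702 and 605, 704 and 493, 280 and 184, and 818 and 538.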

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

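The tests of genomic DNA, array spread, sex, hybridisation and border macrophages were chosen only after the results were seen, while the other splits of the samples were planned. Chance flags about 1 in 20 groups: of 185 groups tested, 10 held a sample far from the others, where 9 would by chance. In young TAU, replicate 4 had an MHC class II mean of 9.32, replicate 2 an astrocyte mean of 8.03 and an oligodendrocyte mean of 7.23, and replicate 1 a Kdm5d signal of 7.71. In young WT, replicate 1 had an Alzheimer risk gene mean of 11.20 and an Apoe signal of 9.85, and replicate 4 an NF-kB mean of 11.28. WT 12 months replicate 1 had an oligodendrocyte mean of 7.24, gated TAU replicate 4 a neuron mean of 7.89 and gated TAU replicate 1 a Trem2 signal of 15.77.

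Differences between groups stood out by a direct test in the interactions (844 probe sets for APP and 832 for TAU) and between the gated groups (206). In the last of these the lists of MHC class II (adjusted p = 1.61e-11), glycolysis and HIF1 target (2.81e-24) and cholesterol synthesis genes (1.58e-23) differed. Each count of probe sets, but no list, was set beside other splits of the same samples into groups of the same sizes. Chance was argued against for gated APP against WT (2015 probe sets, against 1795 in the highest other split, 1 of 35 splits gave as many). The same held for gated TAU against WT (1946 against 426, 1 of 35) and the gated groups (206 against 7, 1 of 35). A share of 1 of 35 is the smallest that these splits can give. Chance was also argued against for the TAU interaction (832 against 604, 1 of 100). For the APP interaction few splits gave as many (3 of 100), but the highest other split gave 1151 against 844, so chance was not excluded. The APP split with 1795 calls exchanged WT 12 months replicate 3 for gated APP replicate 4. In young APP (0 against 1) and young TAU (0 against 0) every split gave as many as the real count by construction (35 of 35 each). The splits therefore cannot decide about chance there, and the fit that called 93 in young APP was not split. Chance could not be excluded for WT with age (8 against 400, 2 of 35). The split with 400 calls set WT 12 months replicates 1, 2 and 4 and WT 3 months replicate 1 against the other 4 WT samples, which points to a structure of the samples.

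Probe sets of multicopy genes on the Y chromosome varied widely among the WT samples, with medians over 37 probe sets from 7.94 to 13.86. Their range over the 4 WT 12 months samples was 5.92, far beyond the 1.02 that was the highest for medians of level-matched autosomal sets, which argues against a narrower spread of all values as the cause. The level matching was changed after a first result had been seen. Genomic DNA in the amplified material may be the source: the Y median followed the median of 1420 chemosensory receptor probe sets over the 8 WT samples (Pearson r = 0.95, exact permutation p = 0.00057). Multicopy X probe sets followed it within groups over the 23 samples (r = 0.849, permutation p = 9e-05). The receptor median also ran against the array SD. It was 6.32 at SD of 2.4 and 2.41 in WT 12 months replicates 2 and 4, and 5.63 at 2.6 in replicate 3. These correlations alone therefore cannot tell genomic DNA from other differences between the arrays. No biological explanation was tested.

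Y-linked transcripts were low in young APP samples (exact p = 0.0286 for the mean of 3 genes, the smallest that 35 splits can give): Uty was at 8.84 ± 0.51 in WT and at background in APP, and Eif2s3y was at background in both, so that the difference has no exact size. Weaker hybridisation of these arrays was argued against by 1825 autosomal probe sets near the WT level of Uty, a matching changed after a first result, whose median log2 fold change was -0.016. Female mice in the young APP group may account for it. The mean of 4 genes that escape X inactivation was 10.6 to 10.85 in young APP and 9.66 to 10.55 in young WT (difference 0.608, exact p = 0.0571). The multicopy Y medians were 6.14 to 6.92 against 8.64 to 10.79. Both go in that direction. Sex would then differ together with strain, so that their effects on other genes cannot be told apart in this comparison. Strain alone is argued against by Uty within strains: 8.38 and 9.11 in gated APP replicates 1 and 2 beside 4.86 in replicate 4, and 8.58 in young TAU replicate 1 beside 4.29 to 5.18 in the other 3. The labels do not give the sex, and Xist was not analysed here.

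MHC class II genes were higher in gated TAU than in gated APP microglia. A larger share of border or perivascular macrophages may contribute to that difference and cannot be told apart from other sources, since the median of their markers was higher by 0.30 (quartiles 0.08 and 0.59) beside 0.81 for MHC class II, and Mrc1, an abundant marker of these cells, was at 10.72 ± 0.72 in TAU and 9.04 ± 0.45 in APP. For the rise in gated TAU over WT the markers had a median of 0.14 (quartiles -0.08 and 0.28) beside 1.58 for MHC class II. Mrc1 was at 10.20 ± 0.33 in WT. The marker set thus did not rise with the MHC class II genes. Its mean signal was 7.72 in WT and 7.73 in TAU, below the levels taken as background (8.14 and 7.87). Some markers lay above these levels and differed little besides Mrc1: Pf4 was at 9.32 ± 0.24 in WT and 9.48 ± 0.46 in TAU. Cbr2 was at 8.89 ± 0.55 and 9.03 ± 0.63, while Stab1 fell. With a marker set this dim on average a larger share of these macrophages cannot be excluded, and the CD45 and CD11b gate would not remove them. Sex was argued against by the adjusted p of 7.42e-12 with the Y-linked mean as a covariate (0.00024 with an estimated correlation) and of 1.94e-08 without the aged samples low in Y-linked transcripts. Strain and the ages of 9 and 12 months were not tested apart.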

How the results depend on the processing

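The 3 covariates and the 2 fits without certain samples were chosen after seeing the data; the other alternatives were planned. No named gene that was called in the main fit reversed. For named genes not called there, a change of sign was not counted as a reversal. Of results for named genes, 133 lost their call and 210 moved (103 with the Y-linked mean and 86 without WT 12 months replicates 2 and 4), and with a sample left out 253 and 78. The MHC class II, glycolysis and cholesterol synthesis calls between the gated groups held under all of these alternatives. Of list results, 744 were the same, 105 lost their call and 9 reversed, and with a sample left out 869, 64 and 2. Fits on the compared groups alone have fewer samples and a spread from those groups only. They called 93 probe sets in young APP (1 higher, 92 lower), where the main fit called 0. They called 5 in WT with age, 1326 in gated APP, 1218 in gated TAU and 120 between the gated groups. For WT with age the count was 3 after centring, 4 after quantile normalization, 13 with array weights, 5 at 2-fold or more and 4 with a symbol. Array weights gave 8 in young APP, 1575 in the APP interaction (62.7% higher, against 74.3%) and 1460 in the TAU interaction. A 2-fold minimum, stricter by construction, gave 1172 for gated APP and 993 for gated TAU. With an estimated correlation 0 lists were called in young APP, young TAU and WT with age, 11 in gated APP and 3 between the gated groups, and fry called 0, 0 and 0 in the first 3. The aged sets in young mice gave 0.486 (APP higher) and 0.361 (TAU higher) with it. The array SD as a covariate left 2 lists in young TAU. The Y-linked mean gave 447 and 502 probe sets in the APP and TAU interactions and 8 lists in young TAU. It reversed in young APP oxidative phosphorylation (adjusted p = 0.00128), NF-kB (0.0364) and ribosomal genes (0.279), and in young TAU lipid (0.975), lysosome (0.566), NF-kB (0.0963) and risk genes (0.438). The receptor median gave 1112 in the APP (58.9% higher) and 1307 in the TAU interaction (53.7% higher, against 69.4%), 49.2% higher in gated TAU and 2 lists in young TAU. The array SD gave 59.7% and 58.8% higher in the interactions, 53.8% in gated APP and 55.6% between the gated groups (against 67.5%). Centring gave 70.6% in gated APP and 66.2% in gated TAU. Without WT 12 months replicate 3 the TAU interaction had 60.3% higher, and without replicates 2 and 4 the interactions had 59.4% and 60.3%. Without WT 12 months replicates 2 and 4 the counts were 1 in WT with age, 1264 in gated APP (49.6% higher, against 61.7%), 1227 in gated TAU (42.2%, against 58.1%) and 464 in the TAU interaction, and lysosome (0.311) and risk genes (0.35) reversed in WT with age. The correlation of the aged changes was 0.887 without dim probe sets, and 0.701, 0.47, 0.74, 0.73, 0.442 and 0.708 with the WT samples split. Leaving out each sample in turn gave 0 to 0 probe sets in young APP, 0 to 1 in young TAU (1 without TAU replicate 3), 0 to 88 in WT with age and 1508 to 2807 in gated APP. The count in WT with age was 0 without WT 3 months replicate 2 or 3, 3 without replicate 1 and 5 without replicate 4, and 5, 4, 88 and 3 without WT 12 months replicates 1, 2, 3 and 4. The ranges were 1396 to 2526 in gated TAU, 147 to 223 between the gated groups, 597 to 1190 in the APP interaction and 541 to 1356 in the TAU interaction (without TAU 3 months replicate 3 and WT 12 months replicate 3). Lists ran from 3 (without APP replicate 2) to 9 in young APP, 1 to 10 in young TAU (1 without TAU replicate 4, 9 without replicate 1 or 2, 10 without WT replicate 1) and 1 to 6 in WT with age (1 without WT 3 months replicate 2, 2 without replicate 3 or WT 12 months replicate 4). They ran from 16 to 18 in gated APP, 14 to 16 in gated TAU, 9 to 12 between the gated groups, 15 to 17 in the APP and 14 to 15 in the TAU interaction. The correlation ran from 0.825 to 0.892. Camera's p for the aged sets in young mice ran from 2.46e-05 to 0.338 for APP higher (0.125 without WT replicate 2, 0.338 without APP replicate 2). It ran from 0.0401 (without APP replicate 1) to 0.792 for APP lower, 3.94e-09 to 0.556 for TAU higher (0.556 without TAU replicate 4) and 0.0522 to 0.886 for TAU lower. APP lower reversed without WT replicate 1 (0.485), WT replicate 4 (0.444) and APP replicate 2 (0.0775). TAU lower reversed without WT replicate 2 (0.756), TAU replicate 1 (0.886) and TAU replicate 4 (0.512). In young APP oxidative phosphorylation genes (4.68e-08 to 0.293 over the samples left out) and ribosomal genes (1.01e-19 to 0.487) reversed without APP replicate 2, at adjusted p of 0.214 and 0.487. The replicate block gave 0, 0, 8, 2344, 2369, 224, 1193 and 1061 probe sets in the order of the contrasts; the numbers were not taken to pair the samples, as same-numbered samples had a mean residual correlation of 0.109 (-0.521 to 0.552), against -0.0366 for others. Of 55 same-numbered pairs 28 exceeded 0.1, and 13 of 23 samples had their best match in another group at their own number, so that pairing was not ruled out. Except where fewer samples or a stricter minimum shows it, the cause was not tested. Signal over background was not available, since background was removed before deposit.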
